A study of Mus musculus with 9 samples.

How the data were processed

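RNA was measured in 9 libraries of bone marrow-derived dendritic cells, 3 unstimulated, 3 infected with GAS and 3 with S. aureus, labelled as mice A, B and C. Per the labels, total RNA was extracted with a column kit, poly(A) RNA was selected and libraries were made for Ion Torrent sequencing. The authors quantified transcripts with kallisto against GRCm38, and their notes also name limma and mm10. Versions, bias settings and strand settings were not given in the sources used here. The deposited tables give estimated counts per transcript. Per the file headers they also give TPM, an abundance scaled for transcript length and depth, and the effective length of each transcript. The effective length equalled the length minus a constant for 50.4% to 54.1% of transcripts and otherwise differed between libraries. TPM served only to weight transcript lengths in 1 alternative.

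The 122968 transcripts belonged to 49585 genes, of which 49326 (99.5%) were found in GENCODE vM21 on GRCm38. Estimated counts were summed per gene and rounded. Genes passed edgeR's expression filter in 12693 cases. Libraries were scaled by the trimmed mean of M-values (TMM), with factors of 1.08 to 1.19 for unstimulated, 0.827 to 0.839 for GAS and 1.04 to 1.09 for S. aureus libraries. All 9 libraries were fitted with 3 group means in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. Errors of log2 fold changes are standard errors (SE), errors of CPM are standard deviations (SD), and n = 3 throughout. Effects of 2 groups were compared through the direct contrast of S. aureus with GAS.

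For a gene at 0 in a whole group the fold is a bound, taken against 3 counts per library averaged over the group, which is 0.188 to 0.358 CPM per library. With 1 to 3 counts the ratio of counts is given with its 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Group shares of library measures were compared by 2-sided exact permutation tests, which cannot go below 0.1 for 3 against 3 libraries.

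The comparisons, 13 panel genes, 29 gene lists and the alternatives were chosen before the data were examined. Genes were named by a rule: the panel, the 10 steepest changes by fitted value in each direction among genes past the threshold, changed the same way in all 3 mice and at 10 CPM or more in a group, and up to 4 genes per list with the smallest p. Some of these genes are not reported here. Lists of at least 3 tested genes, 23 of the 29, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 69 tests. Camera asks whether a list shifted relative to other genes. With an estimated correlation, 0 of the 13 list calls held for GAS, 1 of 14 for S. aureus (antibacterial effectors) and 0 of 12 for S. aureus against GAS. The loss of calls cannot be put down to correlation alone. For antibacterial effectors the camera p rose although the estimate lay under the preset value. The test fry, which asks whether a list moved one way and does not compare it with other genes, passed 18, 14 and 15 lists. Lists of cell type markers and of other functions share some genes with what dendritic cells express.

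Some genes cannot be told from near-identical relatives or from overlapping genes. Art3 overlaps Cxcl10 and Cxcl11 on the opposite strand of chromosome 5, and the strand setting is unknown. Ifit3 and Ifit3b, Ifit1bl1, Oasl1, Apol9b and the guanylate-binding protein family have close paralogs, so the split of counts among them is uncertain.

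Same-group r was 0.907 to 0.972 across 9611 genes, which are not independent replicates. Chi-square per degree of freedom was 11.7 and 17.6 for A with C of GAS and S. aureus, and 48.7 to 108 for other replicates. This excludes only copied libraries. With group means removed, 7 of 9 libraries correlated best within their mouse, and same-mouse r was -0.128 to 0.439. The 3 libraries of mouse B deviated together. No sequencing batch is labelled.

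The pipeline was tested on simulated data with 100 genes changed by 2-fold and 100 by 4-fold. It recovered 20, 31 and 27% of 2-fold and 85, 91 and 88% of 4-fold changes in the 3 comparisons, and 5.41, 5.43 and 6.50% of calls were false. The simulated changes were far fewer than the 1179 to 5365 genes called in the data, and were drawn from genes at 5 CPM or more. The adjustment is stricter with few changes, so these rates do not give the sensitivity in the data. Alternatives were size factors of DESeq2 1.42.0, its Wald test, limma-voom, no filter, a filter of 5 CPM in 3 libraries, mouse as a block, 2-group fits, length offsets, protein-coding genes, a fold of at least 2 and each library left out. Scaling by library totals and leaving out mouse B were chosen after seeing the data. DESeq2 gave no adjusted p for 37 genes in each comparison. Sequence reads were not analysed here.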

Results

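Gene expression was measured by RNA sequencing of poly(A)-selected RNA from dendritic cells grown out of the bone marrow of wild-type C57BL/6 mice. The cells had been cultured for 9 days with 20 ng/ml GM-CSF, the growth factor that drives marrow precursors towards dendritic cells and macrophages. There were 9 libraries in 3 groups of 3: cells left unstimulated, cells infected with group A Streptococcus (GAS, Streptococcus pyogenes strain M49) and cells infected with Staphylococcus aureus (strain LAC). Both infections used 3 bacteria per cell for 1 h, followed by 12 h in medium with 100 μg/ml gentamicin, an antibiotic that kills bacteria outside the cells. The labels give no gentamicin and no matching infection or culture times for the unstimulated cells. Effects of that handling therefore cannot be told apart from infection in comparisons with unstimulated cells. The labels give each group 1 library from each of mice A, B and C. That a letter marks the same mouse in all 3 groups was read from the labels alone, and apart from mouse B the values gave it weak backing, so counts over mice and fits with mouse as a block depend on it.

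The libraries held between 10052542 and 14391387 estimated counts. The group means were 12.5 ± 1.64 M (M, mega) for unstimulated cells, 10.6 ± 0.491 M for GAS and 11.1 ± 0.292 M for S. aureus (mean ± SD, n = 3, as for all group means below). Between 16120 and 17206 genes had at least 1 count per library, and 12693 genes were tested. Lyz2, which encodes the lysozyme of macrophages and other myeloid cells, was the most abundant gene in all 9 libraries, with 2.35% to 4.03% of the counts. Ribosomal protein genes took 4.53 ± 0.691% of the counts in unstimulated cells, 3.15 ± 0.347% after GAS and 3.76 ± 0.214% after S. aureus. The GAS libraries were lower than each of the other groups in this share, at an exact 2-sided permutation p of 0.1 in both comparisons, the smallest that 3 against 3 libraries allow. The 10 most abundant genes took 13.9 ± 0.301% after GAS, 16.2 ± 1.13% after S. aureus and 16.9 ± 0.889% without stimulation. Mitochondrial transcripts took 2.54 ± 1.16%, 2.37 ± 0.862% and 2.12 ± 0.651% in unstimulated, GAS and S. aureus libraries, differences smaller than the spread within groups. A first principal component with 65.1% of the variance placed the S. aureus libraries between the unstimulated and the GAS libraries, and the second component, with 10.4%, set S. aureus apart from both.

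The comparison of GAS with unstimulated cells asked which genes dendritic cells turned on or off in response to this bacterium. GAS infection raised inflammatory cytokines steeply: Tnf, the gene of tumour necrosis factor, rose from 30.3 ± 8.33 to 4074 ± 870.2 CPM (counts scaled to library size), a log2 fold change of 7.07 ± 0.45 (SE, edgeR adjusted p = 4.86e-06). Il6, which encodes a pyrogenic cytokine, rose from 0.468 ± 0.655 to 1224 ± 53.0 CPM (11.41 ± 0.96, edgeR adjusted p = 2.15e-05), and Il12b, the shared subunit of interleukins 12 and 23, from 2.13 ± 1.95 to 1701 ± 448 CPM (9.66 ± 0.99, edgeR adjusted p = 7.14e-05). Ifnb1, which encodes interferon beta, went from 0.216 ± 0.375 to 374 ± 231 CPM (10.84 ± 1.05, edgeR adjusted p = 5.02e-05), and Nos2, the inducible nitric oxide synthase, from 0.620 ± 0.651 to 1259.9 ± 82.9 CPM (11.01 ± 0.79, edgeR adjusted p = 8.64e-06). Of 22 cholesterol genes 18 fell, and of 30 cell cycle genes 23. Of the 12693 genes, 2763 were higher and 2602 lower after GAS at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 42.3% of those tested, and 1944 and 1721 of them changed by 2-fold or more.

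Cytokines, chemokines and interferon-induced genes made up the clearest increases. Of the 18 proinflammatory cytokines tested, 15 rose, 0 fell and 3 did not pass (16 and 0 adjusted over the list alone), at a median log2 fold change of 6.22 (5.12 with genes at 0 held at their bounds, camera adjusted p = 2.84e-10, adjusted p = 0.0837 with an estimated correlation). Its members included Il27 (8.49 ± 0.50), Il1a (5.38 ± 0.34), Il1b (5.22 ± 0.46) and the death ligand gene Tnfsf10 (7.65 ± 0.43). Il23a had 0 counts in unstimulated cells and was at least 18.4-fold higher after GAS (edgeR adjusted p = 0.00824). Among 20 chemokines, 15 rose, 0 fell and 5 did not pass (15 and 0 adjusted over the list alone), at a median of 4.41 (camera adjusted p = 5.02e-09, adjusted p = 0.0837 with an estimated correlation). They included Ccl5 (9.69 ± 0.26), a chemokine for T cells, the neutrophil attractants Cxcl1 (8.83 ± 0.58) and Cxcl2 (8.46 ± 0.59), and the interferon-induced Cxcl10 (11.52 ± 0.83). All 36 type I interferon-induced genes rose, before and adjusted over the list alone, at a median of 5.62 (camera adjusted p = 2.73e-30, adjusted p = 0.0837 with an estimated correlation). Isg15, a ubiquitin-like modifier, rose from 3.94 ± 1.32 to 2105 ± 381 CPM, and Irf7, a transcription factor of the interferon response, from 4.73 ± 0.862 to 1058 ± 78.3 CPM. All 16 guanylate-binding proteins and immunity-related GTPases, which act against bacteria and vacuoles inside cells, also rose, and also adjusted over the list alone, at a median of 5.73 (camera adjusted p = 9.67e-14, adjusted p = 0.134 with an estimated correlation), with Irgm1 at 5.50 ± 0.21 and Gbp4 at 8.22 ± 0.43.

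Genes of dendritic cell maturation and co-stimulation followed: of 18 tested, 16 rose, 1 fell and 1 did not pass (16 and 1 adjusted over the list alone), at a median of 2.81 (camera adjusted p = 1.06e-07, adjusted p = 0.101 with an estimated correlation). Cd40, the receptor through which T cells activate dendritic cells, rose from 0.834 ± 0.754 to 1021 ± 108 CPM (10.29 ± 0.64, edgeR adjusted p = 4.69e-06). The co-stimulatory ligands Cd86 (4.31 ± 0.42, edgeR adjusted p = 5.06e-05) and Cd80 (1.42 ± 0.25, edgeR adjusted p = 0.00147) rose as well. Of 26 negative regulators of inflammation, 19 rose, 3 fell and 4 did not pass (19 and 3 adjusted over the list alone), at a median of 1.80 (camera adjusted p = 8.94e-07, adjusted p = 0.0837 with an estimated correlation). Cd274, which encodes the inhibitory ligand PD-L1, rose by 3.48 ± 0.27, Il1rn, the interleukin 1 receptor antagonist, by 4.14 ± 0.21, and Il10, with 0 counts in unstimulated cells, was at least 54.7-fold higher (edgeR adjusted p = 6.41e-05). MHC class I presentation genes showed the same pattern, since of 18 tested 16 rose, 0 fell and 2 did not pass (16 and 0 adjusted over the list alone), at a median of 2.35 (camera adjusted p = 1.75e-09, adjusted p = 0.0837 with an estimated correlation), among them the peptide transporter Tap1 (4.25 ± 0.25) and the immunoproteasome subunit Psmb9 (3.13 ± 0.17). MHC class II genes did not shift as a group: of 12, 2 rose, 1 fell and 9 did not pass (1 and 1 adjusted over the list alone), at a median of 0.13 (camera adjusted p = 0.862), and the median was -0.31 when libraries were scaled by their totals. H2-Oa (3.64 ± 0.63) and Ctss (0.46 ± 0.16) were the members that rose, and H2-DMb2 (-2.38 ± 0.32) the member that fell.

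Sensors and effectors of bacterial recognition rose in part. Among 28 pattern recognition receptors and adaptors, 15 rose, 2 fell and 11 did not pass (17 and 5 adjusted over the list alone), at a median of 0.89 (camera adjusted p = 0.00071, adjusted p = 0.313 with an estimated correlation). Tlr3, a receptor of double-stranded RNA, rose by 4.32 ± 0.36, Nod1, a sensor of cell wall peptides, by 3.21 ± 0.27, and Clec4e, a receptor of glycolipids, by 6.04 ± 0.56. Of 20 inflammasome and cell death effectors, 12 rose, 1 fell and 7 did not pass (12 and 2 adjusted over the list alone), at a median of 1.33 (camera adjusted p = 8.91e-05, adjusted p = 0.0941 with an estimated correlation), including Casp1 (3.00 ± 0.24) and the necroptosis gene Mlkl (3.01 ± 0.22). Of 20 antibacterial effectors, 11 rose, 0 fell and 9 did not pass (11 and 0 adjusted over the list alone), at a median of 1.10 (camera adjusted p = 0.000248, adjusted p = 0.0837 with an estimated correlation). Acod1, the enzyme that makes itaconate, rose from 13.3 ± 2.51 to 4468 ± 124 CPM. Oxidative stress and metallothionein genes, of which 8 rose, 0 fell and 7 did not pass (9 and 0 adjusted over the list alone), had a median of 1.46 (camera adjusted p = 0.000471, adjusted p = 0.399 with an estimated correlation), with Sod2 at 3.07 ± 0.16 and the heme oxygenase gene Hmox1 at 2.16 ± 0.29. Eicosanoid genes split: of 15, 4 rose, 7 fell and 4 did not pass (4 and 8 adjusted over the list alone), with a median of -0.62, a mean of 0.06 and no call for the list (camera adjusted p = 0.137), though it passed with no filter (0.0489) and fry (0.0098). Ptgs2 (10.42 ± 1.18) and Ptges (3.95 ± 0.42), the inducible enzymes of prostaglandin E2 synthesis, rose, and the constitutive Ptgs1 (-2.15 ± 0.18) and the prostaglandin E2 receptor gene Ptger4 (-2.16 ± 0.25) fell.

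Genes of cholesterol synthesis and uptake and of the cell cycle were lower after GAS. Of 22 cholesterol genes, 0 rose, 18 fell and 4 did not pass (0 and 18 adjusted over the list alone), at a median of -1.0 (camera adjusted p = 9.97e-08, adjusted p = 0.144 with an estimated correlation). Dhcr7, the last enzyme of cholesterol synthesis by the Kandutsch-Russell route, fell from 82.1 ± 8.31 to 9.06 ± 1.93 CPM (-3.18 ± 0.21, edgeR adjusted p = 5.69e-06), and the sterol carrier gene Stard4 from 69.0 ± 21.0 to 9.08 ± 1.76 CPM. Of 30 cell cycle genes, 1 rose, 23 fell and 6 did not pass (1 and 25 adjusted over the list alone), at a median of -1.89 (camera adjusted p = 1.16e-07, adjusted p = 0.313 with an estimated correlation). Rrm2, which supplies deoxynucleotides, fell by 3.43 ± 0.40 and Mcm2, of the replicative helicase, by 2.45 ± 0.31 on the log2 scale. Of 32 genes of the TCA cycle and respiratory chain, 1 rose, 9 fell and 22 did not pass (1 and 8 adjusted over the list alone), at a median of -0.14 (camera adjusted p = 0.0573), led by Idh1 (-2.47 ± 0.18), a cytosolic isocitrate dehydrogenase. This list passed with no filter (0.0026), a 5 CPM filter (0.0423), library totals (0.00125) and fry (0.00623), its median being -0.58 with library totals. Leaving out unstimulated library A or GAS library A or C also brought it under the threshold (camera adjusted p = 0.0188, 0.0476 and 0.0362). Of 20 glycolysis and glucose uptake genes, 6 rose, 2 fell and 12 did not pass (6 and 2 adjusted over the list alone), with a median of -0.03, a mean of 0.37 and no call for the list (camera adjusted p = 0.363), and Pfkfb3, an activator of glycolysis, rose by 2.85 ± 0.17. Of 28 lysosome genes, 6 rose, 2 fell and 20 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.666), and Ctsc, the activator of granule proteases, rose by 1.87 ± 0.23. Of 19 genes of the unfolded protein and integrated stress responses, 3 rose, 2 fell and 14 did not pass (2 and 2 adjusted over the list alone, camera adjusted p = 0.83), with the chaperone gene Hspa5 higher by 1.93 ± 0.24 and Pdia4 at -0.78 ± 0.19.

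Lists of cell type markers held no call by camera after GAS, while fry passed the neutrophil (median 0.48, adjusted p = 0.0188) and macrophage lists (median -0.02, adjusted p = 0.0439). Of 4 neutrophil markers tested, 0 passed by edgeR (camera adjusted p = 0.718, 1 at an unadjusted p under 0.05), where S100a8 (1.20 ± 0.51, edgeR adjusted p = 0.0839) passed without unstimulated library B (adjusted p = 0.0269) and with DESeq2 (0.046), limma-voom (0.0427), mouse as a block (0.014) and mouse B left out (0.0297). Csf3r, named after its values were seen, passed with length offsets (0.0473). Of 11 macrophage markers, 3 rose, 2 fell and 6 did not pass (3 and 2 adjusted over the list alone, camera adjusted p = 0.726). Fcgr1, an Fc receptor, was higher by 3.17 ± 0.25, and Csf1r, the receptor of macrophage colony-stimulating factor, was at -0.57 ± 0.15. Of 12 conventional dendritic cell markers, 3 rose, 3 fell and 6 did not pass (3 and 3 adjusted over the list alone, camera adjusted p = 0.862), with Xcr1, a chemokine receptor of cross-presenting dendritic cells, higher by 6.01 ± 0.50 and Irf4, a transcription factor, at -1.74 ± 0.24. Of 6 stromal and endothelial markers, 1 rose, 0 fell and 5 did not pass (1 and 0 adjusted over the list alone), at a median of -1.76 (camera adjusted p = 0.883), the call being Kdr (4.54 ± 0.95). With mouse as a block Col3a1 (-3.02, edgeR adjusted p = 0.0343) and Sparc (-3.69, 0.0247) also passed as lower and Cdh5 (1.56, 0.0135) as higher, genes named here after their values were seen. Lists with fewer than 3 tested genes were counted without a list test. Of 2 plasmacytoid dendritic cell markers Tcf4 rose (3.09 ± 0.31), of 2 mast cell and basophil markers Hdc rose (338-fold by counts, 95% interval 60.1 to 13427, on 1 count in unstimulated cells), and of 2 eosinophil markers Siglecf fell (-0.93 ± 0.24). The B cell marker Ighm fell (-3.20 ± 0.78), of 2 T and NK cell markers Lck rose (3.21 ± 0.77) and Cd28 fell (-4.79 ± 0.84), and 0 of the 11 erythroid markers had enough counts to be tested.

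Among the steepest increases by fitted value were those of Cxcl10, Il6, Art3, Ifit1bl1, Cxcl9, Nos2 and Ifnb1. Art3 and Cxcl9 had 1 count each in unstimulated cells, for count ratios of 3907 (95% interval 701 to 154392) and 3154 (565 to 124636). Clic5, a chloride channel gene on chromosome 17 (44188584 to 44280172, GRCm38), Apol9b on chromosome 15 (77729039 to 77736382) and the olfactory receptor gene Olfr1028 had 0 counts in unstimulated cells. They were at least 408-fold, 275-fold and 77.5-fold higher after GAS (edgeR adjusted p = 0.000245, 1.56e-05 and 6.57e-05), bounds that do not rank them against the others. Among the steepest decreases were Cnr2, the cannabinoid receptor of immune cells, on chromosome 4 (135895394 to 135920207), which fell from 46.3 ± 9.59 to 1.32 ± 0.270 CPM (-5.12 ± 0.30, edgeR adjusted p = 3.57e-06), and Il16, a chemoattractant cytokine gene, which fell from 17.2 ± 8.71 to 0.440 ± 0.467 CPM. Pald1 (-5.42 ± 0.52), Tns4 (-5.41 ± 0.49), the glycosyltransferase gene Galnt9 (-5.22 ± 0.46), the transporter gene Slco2b1 (-4.99 ± 0.62), Tmem154 (-4.92 ± 0.29), Cbfa2t3 (-4.76 ± 0.30) and the potassium channel gene Kcnn3 (-4.74 ± 0.26) fell too, as did Ankrd63, which kept 2 counts after GAS, a 142-fold fall by counts (95% interval 39.0 to 1173). The rule for naming these genes required the same direction in 3 of 3 mice, so that agreement is no separate support.

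These changes are relative to the centre that trimmed-mean scaling sets. With library totals alone the median of all genes moved from -0.02 to -0.45, the share of changed genes that were higher from 51.5% to 27.9%, and the calls to 1818 higher and 4708 lower, while cytokine, interferon and cholesterol lists kept their direction and their calls. Calls of genes named above that a single library ended were those of Ctss (unstimulated A or C or GAS A or C, 0.0775 to 0.136), Csf1r (GAS A, 0.0504) and Siglecf (GAS C, 0.0545), each given with the left-out library and the edgeR adjusted p without it. Other alternatives also ended calls of these genes, with the adjusted p, those of Ctss (0.25) with no filter, Ighm (0.0813) with limma-voom, Ctss (0.0731) with length offsets, Ctss (0.922) with library totals and Ctss (0.0783) with 2-group fits. Among list members not named above they ended those of Clec9a (0.157) with length offsets and Mertk (0.0726), Axl (0.146), Irf8 (0.21), Uqcrfs1 (0.0663) and Atf3 (0.172) with library totals. Further list members that passed with mouse as a block were Gclm (0.78, 0.0168) and Panx1 (0.71, 0.018).

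**Figure D1:**
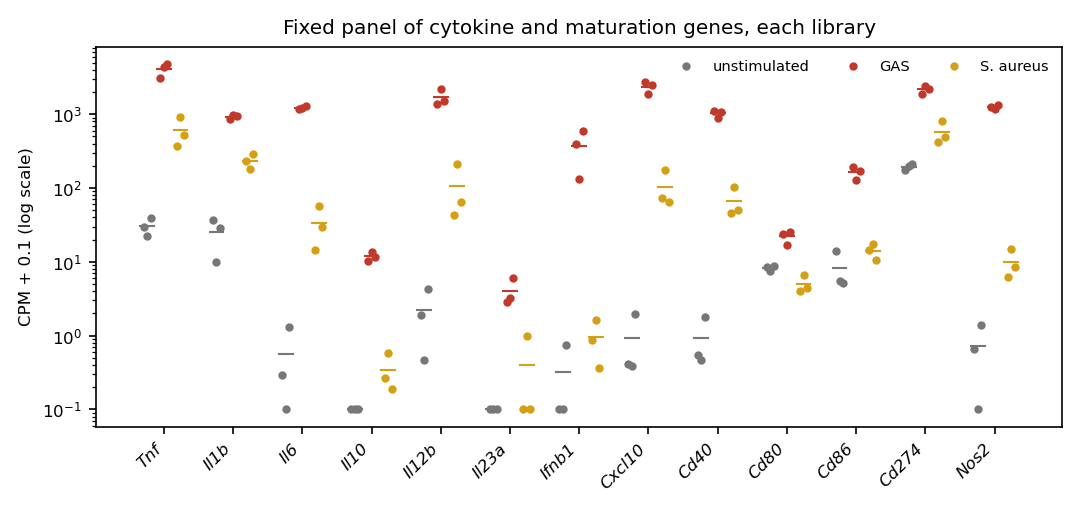
CPM of the 13 panel genes on a log axis, with 0.1 added; points are the 3 libraries of each group and bars their mean. Tnf reached 4074 CPM after GAS and 606 CPM after S. aureus, and Ifnb1 374 and 0.854 CPM.

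The comparison of S. aureus with unstimulated cells asked the same of the second bacterium. S. aureus raised the neutrophil attractant genes Cxcl3, from 4.09 ± 2.13 to 666 ± 186 CPM (7.35 ± 0.53, edgeR adjusted p = 5.33e-05), and Cxcl2, from 3.80 ± 1.07 to 481 ± 243 CPM (6.98 ± 0.56, edgeR adjusted p = 9.85e-05). Tnf rose to 606 ± 283 CPM (4.32 ± 0.39, edgeR adjusted p = 0.000192) and Il6 to 33.5 ± 21.9 CPM (6.22 ± 0.84, edgeR adjusted p = 0.00147). All 36 type I interferon-induced genes tested rose, Isg15 to 226 ± 35.0 CPM (5.84 ± 0.30, edgeR adjusted p = 1.65e-05), although Ifnb1 itself stood at 0.854 ± 0.632 CPM against 0.216 ± 0.375 CPM and did not pass (2.10 ± 1.24, edgeR adjusted p = 0.371). With an unstimulated mean at about the floor, a small rise of Ifnb1 cannot be told from none. Acod1 rose to 1582 ± 201 CPM and the antioxidant gene Hmox1 to 1866 ± 162 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 852 genes were higher and 327 lower, 9.29% of those tested, of which 667 and 208 changed by 2-fold or more.

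Of the 18 proinflammatory cytokines, 11 rose, 0 fell and 7 did not pass (13 and 2 adjusted over the list alone), at a median of 2.95 (2.10 with genes at 0 held at their bounds, camera adjusted p = 7.45e-09, adjusted p = 0.0837 with an estimated correlation), with Il1b at 3.24 ± 0.42, Il12b at 5.67 ± 0.85 and Tnfsf10 at 4.91 ± 0.40. Il23a had 0 counts in unstimulated cells and 0.293 ± 0.508 CPM after S. aureus, and did not pass (edgeR adjusted p = 0.213). Among 20 chemokines, 9 rose, 1 fell and 10 did not pass (11 and 4 adjusted over the list alone), at a median of 1.81 (camera adjusted p = 1.03e-06, adjusted p = 0.109 with an estimated correlation). Ccl5 rose by 4.85 ± 0.22 and Cxcl1 by 6.54 ± 0.55, Cxcl5, with 0 counts in unstimulated cells, was at least 68.3-fold higher (edgeR adjusted p = 0.000461), and the member that fell was the monocyte attractant gene Ccl2 (-2.20 ± 0.59), named here after its values were seen. All 36 type I interferon-induced genes rose, before and adjusted over the list alone, at a median of 3.83 (camera adjusted p = 1.55e-55, adjusted p = 0.0837 with an estimated correlation). Among them were Irf7 (5.43 ± 0.24), Cmpk2 (6.26 ± 0.32) and Oas2 (4.83 ± 0.26), a sensor of double-stranded RNA. Of 16 guanylate-binding proteins and immunity-related GTPases, 15 rose, 0 fell and 1 did not pass (15 and 0 adjusted over the list alone), at a median of 3.60 (camera adjusted p = 8.75e-20, adjusted p = 0.0941 with an estimated correlation), with Irgm1 at 3.33 ± 0.19 and Gbp5 at 4.82 ± 0.41. Of 18 MHC class I presentation genes, 11 rose, 0 fell and 7 did not pass (13 and 0 adjusted over the list alone), at a median of 1.17 (camera adjusted p = 1.04e-09, adjusted p = 0.0837 with an estimated correlation), with Tap1 at 2.65 ± 0.23. Of 12 MHC class II genes, 1 rose, 1 fell and 10 did not pass (1 and 1 adjusted over the list alone), at a median of 0.14 (camera adjusted p = 0.83), H2-Oa (2.51 ± 0.62) having risen and H2-DMb2 (-1.97 ± 0.30) having fallen.

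Of 18 maturation and co-stimulation genes, 9 rose, 1 fell and 8 did not pass (9 and 2 adjusted over the list alone), at a median of 1.66 (camera adjusted p = 1.99e-07, adjusted p = 0.105 with an estimated correlation). Cd40 rose to 65.9 ± 31.3 CPM (6.34 ± 0.57, edgeR adjusted p = 0.000173), the adhesion gene Icam1 by 1.78 ± 0.17, and Socs2 fell by 2.50 ± 0.19 on the log2 scale. Cd86 stood at 14.0 ± 3.45 CPM (0.77 ± 0.38, edgeR adjusted p = 0.27) and Cd80 at 4.91 ± 1.44 CPM (-0.73 ± 0.25, edgeR adjusted p = 0.11), and neither passed. Cd86 did pass without unstimulated library A (1.41, edgeR adjusted p = 0.0158), and Cd80 without the 3 libraries of mouse B (-1.06, edgeR adjusted p = 0.0311). Of 26 negative regulators of inflammation, 12 rose, 2 fell and 12 did not pass (18 and 3 adjusted over the list alone), at a median of 1.23 (1.02 with genes at 0 held at their bounds, camera adjusted p = 1.16e-07, adjusted p = 0.0837 with an estimated correlation). Nfkbia, the inhibitor of NF-κB, rose by 2.20 ± 0.15 and Cd274 by 1.56 ± 0.25, and Cish, an inhibitor of cytokine receptor signalling, fell from 90.5 ± 36.7 to 9.60 ± 0.159 CPM. Il10 had 0 counts in unstimulated cells and 0.247 ± 0.206 CPM after S. aureus, at least 1.15-fold higher (edgeR adjusted p = 0.0349).

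Antibacterial effector genes formed the list whose call also held with an estimated correlation. Of 20, 10 rose, 0 fell and 10 did not pass (12 and 0 adjusted over the list alone), at a median of 1.24 (camera adjusted p = 1.75e-09, adjusted p = 0.0326 with an estimated correlation). Saa3, an acute phase protein gene, rose from 2.37 ± 0.881 to 119.9 ± 54.0 CPM, Lcn2, whose product binds bacterial siderophores, from 0.820 ± 0.617 to 9.98 ± 2.00 CPM, and Nos2 to 9.70 ± 4.41 CPM (3.99 ± 0.67, edgeR adjusted p = 0.00475). Of 15 oxidative stress and metallothionein genes, 8 rose, 0 fell and 7 did not pass (13 and 0 adjusted over the list alone), at a median of 1.81 (camera adjusted p = 1.68e-12, adjusted p = 0.112 with an estimated correlation), with Hmox1 at 2.54 ± 0.30, Sqstm1 at 2.32 ± 0.22 and Prdx1 at 1.48 ± 0.17. Of 28 pattern recognition receptors and adaptors, 11 rose, 0 fell and 17 did not pass (11 and 1 adjusted over the list alone), at a median of 0.47 (camera adjusted p = 2.61e-05, adjusted p = 0.218 with an estimated correlation), including Clec4e (4.97 ± 0.54) and Nod2 (2.19 ± 0.27), a sensor of muramyl dipeptide. Of 20 inflammasome and cell death effectors, 10 rose, 0 fell and 10 did not pass (12 and 1 adjusted over the list alone), at a median of 0.91 (camera adjusted p = 6.12e-06, adjusted p = 0.0837 with an estimated correlation), including Casp1 (1.66 ± 0.23) and Casp4 (2.49 ± 0.36).

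Metabolic and cell cycle lists held few calls. Of 22 cholesterol genes, 0 rose, 1 fell and 21 did not pass (0 and 0 adjusted over the list alone), the call being Dhcr7 (-0.76 ± 0.19), at a median of 0.24 (camera adjusted p = 0.239). This list passed with mouse B left out (0.0147) and without unstimulated library B (median 0.36, camera adjusted p = 0.0425). Of 30 cell cycle genes, 0 rose, 3 fell and 27 did not pass (0 and 8 adjusted over the list alone), at a median of -0.74 (camera adjusted p = 1.6e-06, adjusted p = 0.359 with an estimated correlation), the calls being the cyclin gene Ccne2 (-1.82 ± 0.45), Rrm2 (-1.40 ± 0.36) and Rrm1 (-1.04 ± 0.28). The cell cycle list did not pass with fry (adjusted p = 0.0906). Of 32 TCA cycle and respiratory chain genes, 0 rose, 2 fell and 30 did not pass (0 and 2 adjusted over the list alone), at a median of -0.17 (camera adjusted p = 0.000161, adjusted p = 0.144 with an estimated correlation), the calls being Idh3a (-0.93 ± 0.16) and Sdhd (-0.68 ± 0.16). Of 20 glycolysis genes, 2 rose, 1 fell and 17 did not pass (2 and 2 adjusted over the list alone, camera adjusted p = 0.855), namely Slc2a6 (1.98 ± 0.19) and Pfkfb3 (0.92 ± 0.16) up and the lactate transporter gene Slc16a1 (-1.02 ± 0.27, edgeR adjusted p = 0.0437, and 0.054 with mouse as a block) down. Of 15 eicosanoid genes, 2 rose, 2 fell and 11 did not pass (2 and 4 adjusted over the list alone), with a median of -0.42, a mean of 0.12 and no call for the list (camera adjusted p = 0.0842, and under 0.05 with no filter (0.0206), mouse as a block (0.0469) and length offsets (0.0444)). Ptgs2 (6.51 ± 1.03) and Ptges (2.75 ± 0.41) rose, and Ptgs1 (-1.41 ± 0.18) and the leukotriene A4 hydrolase gene Lta4h (-0.94 ± 0.18) fell. Of 19 genes of the unfolded protein and integrated stress responses, 1 rose, 3 fell and 15 did not pass (1 and 3 adjusted over the list alone), at a median of -0.16 (camera adjusted p = 0.0511, and 0.0463 with mouse as a block), namely Ppp1r15a (1.73 ± 0.31) up and Pdia4 (-1.28 ± 0.20), Xbp1 (-0.95 ± 0.19) and Sesn2 (-1.38 ± 0.33) down. It also passed with no filter (0.0118), length offsets (0.0444) and mouse B left out (0.0115), and without unstimulated library A or S. aureus library B (camera adjusted p = 0.0337 and 0.00772). Of 28 lysosome genes, 0 rose, 1 fell and 27 did not pass (0 and 1 adjusted over the list alone, camera adjusted p = 0.601), the call being the proton pump subunit Atp6v0d2 (-0.90 ± 0.20).

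Of 12 conventional dendritic cell markers, 1 rose, 1 fell and 10 did not pass (1 and 4 adjusted over the list alone), at a median of -0.67 (camera adjusted p = 0.0276, adjusted p = 0.224 with an estimated correlation), Irf4 having fallen from 61.2 ± 10.6 to 10.2 ± 3.20 CPM (-2.58 ± 0.25, edgeR adjusted p = 0.000255) and Xcr1 having risen (2.10 ± 0.51). The list did not pass without unstimulated library B (median -0.32, camera adjusted p = 0.0547) or S. aureus library B (-0.50, 0.0508), nor with length offsets (-0.72, 0.0564) or mouse B left out (-0.30, 0.07). Of 11 macrophage markers, 2 rose, 1 fell and 8 did not pass (3 and 1 adjusted over the list alone, camera adjusted p = 0.703), with Csf1r (0.76 ± 0.15) and Fcgr1 (0.96 ± 0.24, edgeR adjusted p = 0.0347, and 0.0507 with mouse as a block) higher and the mannose receptor gene Mrc1 (-1.09 ± 0.28) lower. Of 4 neutrophil markers, 0 passed by edgeR (camera adjusted p = 0.324, 1 at an unadjusted p under 0.05, 1 higher and 0 lower adjusted over the list alone), while fry passed the list (median 0.65, adjusted p = 0.00566). The protease gene Mmp9 (1.84 ± 0.52, edgeR adjusted p = 0.06) passed with no filter (0.0326), DESeq2 (0.00967), limma-voom (0.037), mouse as a block (0.00628), mouse B left out (0.0237), 2-group fits (0.0489) and protein-coding genes alone (0.0361). Of 6 stromal and endothelial markers, 0 passed by edgeR (camera adjusted p = 0.352, 0 at an unadjusted p under 0.05) at a median of -1.66, and 0 of them adjusted over the list alone. Tcf4 (1.30 ± 0.29) and Hdc (45.2-fold by counts, 95% interval 7.64 to 1832) rose, 1 each of 2 plasmacytoid and 2 mast cell and basophil markers, and 0 of 2 eosinophil, 1 B cell and 2 T and NK cell markers passed by edgeR. Adjusted over the list alone, 1 plasmacytoid, 1 mast cell and basophil and 1 T and NK cell marker were lower, and 1 T and NK cell marker higher.

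Among the steepest increases after S. aureus were those of Cxcl3, Ifit3 (7.25 ± 0.55), Ifit3b (7.08 ± 0.63), Oasl1 (7.03 ± 0.70), Cxcl10 (7.03 ± 0.72), Cxcl2, Ifit2 (6.92 ± 0.45), Acod1 (6.90 ± 0.24) and Ifit1bl1 (6.87 ± 0.75). Cxcl5 on chromosome 5, with the bound given above, cannot be ranked against them. Among the steepest decreases were Slco2b1 (-4.24 ± 0.58), Eps8 (-3.85 ± 0.25), an actin-capping protein gene that fell from 152 ± 20.0 to 10.5 ± 1.89 CPM, Hs3st3b1 (-3.79 ± 0.48), Scel (-3.65 ± 0.34), Amigo2 (-3.53 ± 0.53), Cish (-3.23 ± 0.27) and Gpr171 (-3.17 ± 0.46). The transcription factor genes Klf4, which fell from 73.2 ± 4.52 to 8.50 ± 1.44 CPM (-3.10 ± 0.18), and Vdr, the vitamin D receptor (-3.01 ± 0.50), and Arg1, which encodes arginase (-2.81 ± 0.62), completed the 10 steepest decreases under the rule for naming genes. That all of these changed in the stated direction in 3 of 3 mice was a condition of the rule and no separate support.

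The total of 1179 genes fell to 761 and 704 without S. aureus library B or C, and the 327 lower genes to 184, 166 and 113 without S. aureus library A, B or C, against 569 lower genes with DESeq2. Calls of named genes that a single left-out library ended, with that library and the edgeR adjusted p without it, were those of Il10 (unstimulated A, B or C or S. aureus A or B, 0.0595 to 0.124), Ccl2 (unstimulated A or C or S. aureus A, B or C, 0.101 to 0.159), Arg1 (S. aureus A, B or C, 0.0609 to 0.0933), H2-Oa (unstimulated A, B or C or S. aureus B or C, 0.0509 to 0.124), Dhcr7 (unstimulated A, B or C or S. aureus B or C, 0.0618 to 0.141), Ccne2 (unstimulated A or B or S. aureus A, B or C, 0.0591 to 0.143), Rrm2 (unstimulated A or B or S. aureus A, B or C, 0.0535 to 0.156), Rrm1 (unstimulated A or B or S. aureus A, B or C, 0.0737 to 0.18), Sdhd (unstimulated A or B or S. aureus A, B or C, 0.0563 to 0.127), and likewise of Slc16a1 (unstimulated A or B or S. aureus A, B or C, 0.063 to 0.15), Lta4h (S. aureus C, 0.0521), Xbp1 (S. aureus A or C, 0.0587 to 0.0701), Sesn2 (unstimulated A or C or S. aureus B or C, 0.0707 to 0.114), Atp6v0d2 (unstimulated A or B or S. aureus A or C, 0.0523 to 0.0914), Xcr1 (unstimulated B or C or S. aureus A or C, 0.0782 to 0.102), Csf1r (S. aureus C, 0.0635), Fcgr1 (unstimulated A or B or S. aureus A or B, 0.0862 to 0.116), Mrc1 (unstimulated A, B or C or S. aureus A or C, 0.0525 to 0.166) and Tcf4 (unstimulated B or C or S. aureus B, 0.0688 to 0.0787). Other alternatives ended calls of named genes too, given here with the adjusted p. Limma-voom ended those of Arg1 (0.0743), Ccl2 (0.0977), Ccne2 (0.0862), H2-Oa (0.118), Il10 (0.122), Ptgs2 (0.0759), Rrm2 (0.0586), Slc16a1 (0.0583) and Xcr1 (0.232), mouse as a block those of Fcgr1 (0.0507) and Slc16a1 (0.054), and length offsets those of Dhcr7 (0.131), Fcgr1 (0.152), Rrm2 (0.103) and Xbp1 (0.0548). Fits of 2 groups alone ended those of Arg1 (0.0507), Atp6v0d2 (0.05), Ccl2 (0.0778), Ccne2 (0.0787), Fcgr1 (0.067), H2-Oa (0.082), Mrc1 (0.0754), Rrm1 (0.0751), Rrm2 (0.0832), Slc16a1 (0.0655) and Tcf4 (0.065). Leaving out mouse B ended those of Arg1 (0.0828), Ccne2 (0.161), Dhcr7 (0.118), Fcgr1 (0.174), H2-Oa (0.15), Il10 (0.182), Lta4h (0.0807), Pfkfb3 (0.0545), Ppp1r15a (0.087), Rrm1 (0.25), Rrm2 (0.259), Slc16a1 (0.0718), Tcf4 (0.128) and Xcr1 (0.053). Members of lists that passed with mouse as a block but not by the first fit (log2 fold change, edgeR adjusted p), named after their values were seen, were Adgre1 (1.31, 0.004), Clec9a (-0.94, 0.0457), H2-DMa (-0.85, 0.00742), Ighm (-1.39, 0.00843), Mcm7 (-1.25, 0.0353) and Pdk1 (-1.12, 0.0254).

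**Figure D2:**
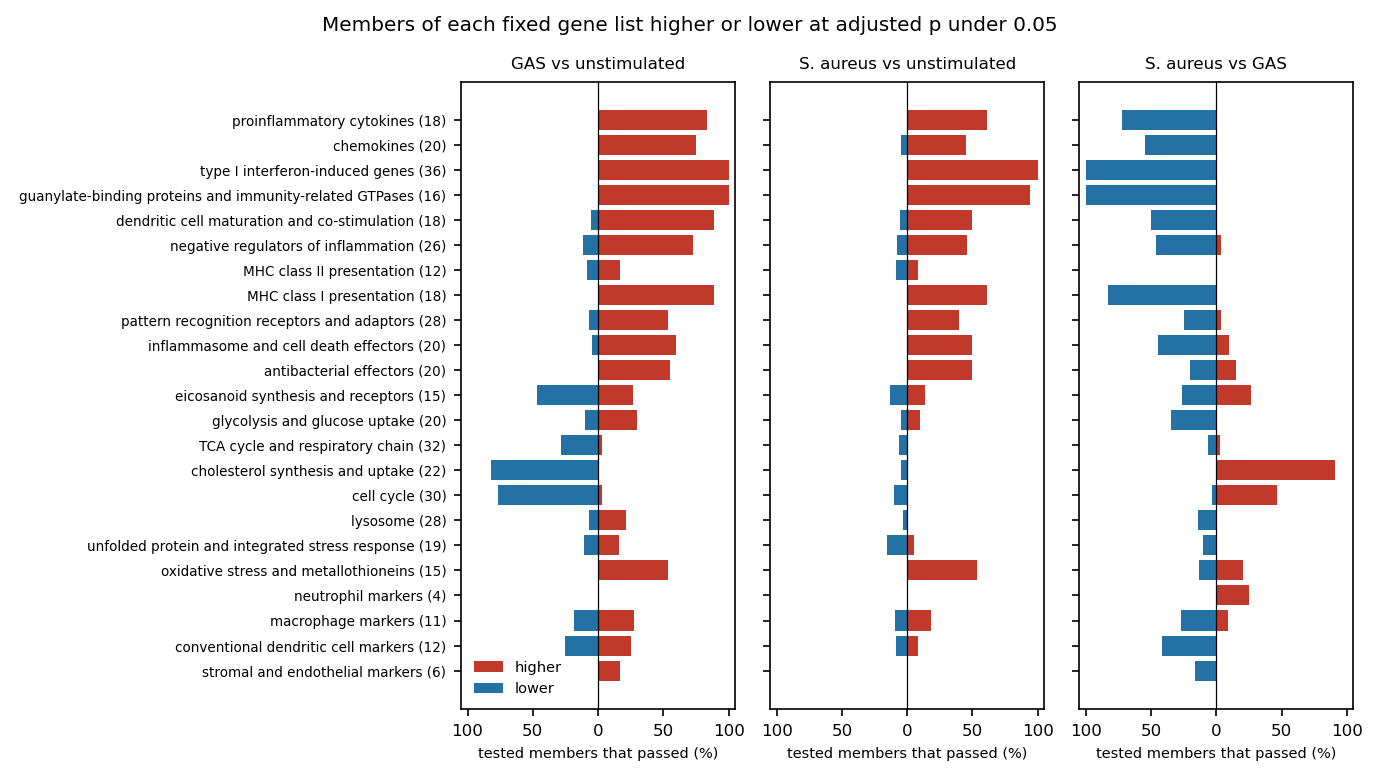
Percentage of the tested members of each gene list that were higher (right, red) or lower (left, blue) at an adjusted p under 0.05, in each comparison, with the number of tested genes in brackets. All 36 type I interferon-induced genes were higher after either infection and lower after S. aureus than after GAS, and 20 of 22 cholesterol genes were higher after S. aureus than after GAS.

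The comparison of S. aureus with GAS asked which genes responded differently to the 2 bacteria, and it tests that difference directly. Ifnb1 stood at 374 ± 231 CPM after GAS and 0.854 ± 0.632 CPM after S. aureus, a log2 fold change of -8.74 ± 0.92 (edgeR adjusted p = 0.000373). Nos2 was at 1259.9 ± 82.9 against 9.70 ± 4.41 CPM (-7.02 ± 0.65, edgeR adjusted p = 0.000246) and Il6 at 1224 ± 53.0 against 33.5 ± 21.9 CPM (-5.19 ± 0.70, edgeR adjusted p = 0.000986). Cd86 was lower after S. aureus, at -3.54 ± 0.40 (edgeR adjusted p = 0.000497), and so was Cd40, at -3.95 ± 0.47 (edgeR adjusted p = 0.000585). The cholesterol gene Dhcr7 went the other way, standing at 48.7 ± 7.98 CPM after S. aureus against 9.06 ± 1.93 CPM after GAS (2.43 ± 0.20, edgeR adjusted p = 0.000202). Each of these differences had the same direction in all 3 mice. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1500 genes were higher and 1774 lower after S. aureus than after GAS, 25.8% of those tested, and 941 and 1158 of them differed by 2-fold or more.

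Inflammatory and interferon-induced genes were lower after S. aureus. Among 18 proinflammatory cytokines, 0 were higher after S. aureus, 13 were lower and 5 did not pass (0 and 15 adjusted over the list alone), at a median of -2.79 (camera adjusted p = 2.26e-10, adjusted p = 0.0837 with an estimated correlation), with Tnf at -2.75 ± 0.36, Il12b at -3.99 ± 0.76 and Il1b at -1.98 ± 0.40. For the 20 chemokines, 0 were higher after S. aureus, 11 were lower and 9 did not pass (1 and 12 adjusted over the list alone), at a median of -1.88 (camera adjusted p = 1.26e-06, adjusted p = 0.109 with an estimated correlation), with Ccl5 at -4.85 ± 0.20 and Ccl4, an attractant of monocytes, at -5.25 ± 0.51. All 36 type I interferon-induced genes were lower, before and adjusted over the list alone, at a median of -1.99 (camera adjusted p = 5.67e-22, adjusted p = 0.108 with an estimated correlation), Isg15 at -3.22 ± 0.26 and Cmpk2, a mitochondrial nucleotide kinase, at -3.47 ± 0.28. All 16 guanylate-binding proteins and immunity-related GTPases were lower too, before and adjusted over the list alone, at a median of -2.39 (camera adjusted p = 5.07e-12, adjusted p = 0.149 with an estimated correlation). In the maturation and co-stimulation list of 18 genes, 0 were higher after S. aureus, 9 were lower and 9 did not pass (0 and 12 adjusted over the list alone), at a median of -1.70 (camera adjusted p = 6.71e-06, adjusted p = 0.134 with an estimated correlation). In the list of 26 negative regulators, 1 was higher after S. aureus, 12 were lower and 13 did not pass (1 and 12 adjusted over the list alone), at a median of -0.90 (camera adjusted p = 4.36e-05, adjusted p = 0.0837 with an estimated correlation), with Il1rn at -3.29 ± 0.20 and Cd274 at -1.92 ± 0.26.

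Among 18 MHC class I presentation genes, 0 were higher after S. aureus, 15 were lower and 3 did not pass (0 and 16 adjusted over the list alone), at a median of -1.25 (camera adjusted p = 1.21e-08, adjusted p = 0.0837 with an estimated correlation), with Tap1 at -1.60 ± 0.22. No difference passed among the 12 MHC class II genes, where 0 differed by edgeR, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.998). For 20 inflammasome and cell death effectors, 2 were higher after S. aureus, 9 were lower and 9 did not pass (2 and 9 adjusted over the list alone), at a median of -0.47 (camera adjusted p = 0.00434, adjusted p = 0.154 with an estimated correlation), with Mlkl at -1.84 ± 0.21. For 28 pattern recognition receptors and adaptors, 1 was higher after S. aureus, 7 were lower and 20 did not pass (3 and 9 adjusted over the list alone), at a median of -0.35 (camera adjusted p = 0.0343, adjusted p = 0.504 with an estimated correlation), with Tlr3 at -2.65 ± 0.33 and the signalling kinase gene Irak1 at 0.92 ± 0.16. This last median was 0.00 with library totals alone, and the list did not pass without GAS library B (0.156) or S. aureus library A (0.087), with length offsets (0.107) or with mouse B left out (0.0546). Among 20 antibacterial effectors, 3 were higher after S. aureus, 4 were lower and 13 did not pass (3 and 4 adjusted over the list alone, camera adjusted p = 0.726), with Acod1 at -1.50 ± 0.19 and Slc11a1, a metal transporter of phagosomes, at 0.94 ± 0.17.

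Most cholesterol genes and 14 of 30 cell cycle genes were higher after S. aureus than after GAS. Of 22 cholesterol genes, 20 were higher after S. aureus, 0 were lower and 2 did not pass (20 and 0 adjusted over the list alone), at a median of 1.38 (camera adjusted p = 3.18e-13, adjusted p = 0.0837 with an estimated correlation), with Stard4 at 2.59 ± 0.25 and Mvd, of the mevalonate pathway, at 1.89 ± 0.23. Of 30 cell cycle genes, 14 were higher after S. aureus, 1 was lower and 15 did not pass (20 and 1 adjusted over the list alone), at a median of 1.14 (camera adjusted p = 1.18e-05, adjusted p = 0.399 with an estimated correlation), with Cdc20, an activator of the anaphase-promoting complex, at 3.11 ± 0.52 and Rrm2 at 2.03 ± 0.38. Oxidative stress and metallothionein genes split, since of 15, 3 were higher after S. aureus, 2 were lower and 10 did not pass (3 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.193). The glutathione synthesis gene Gclm (1.16 ± 0.32), the sulfiredoxin gene Srxn1 (0.98 ± 0.30) and G6pdx (0.77 ± 0.19), which supplies NADPH, were higher. Sod2 (-0.58 ± 0.15) and Prdx1, singled out after its values were seen (-0.52 ± 0.16), were lower. Of 15 eicosanoid genes, 4 were higher after S. aureus, 4 were lower and 7 did not pass (5 and 4 adjusted over the list alone, camera adjusted p = 0.486), with Ptgs2 at -3.91 ± 0.86 and Ptger4 at 1.60 ± 0.25. Of 20 glycolysis genes, 0 were higher after S. aureus, 7 were lower and 13 did not pass (0 and 7 adjusted over the list alone, camera adjusted p = 0.0573), with Pfkfb3 at -1.94 ± 0.16, and the list passed with no filter (0.0302), mouse as a block (0.0372) and length offsets (0.0435) and without GAS library B (0.0159) or S. aureus library A (0.0109). The oxidative stress list passed with mouse B left out (0.0191) and without GAS library B (0.00933).

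Of 32 TCA cycle and respiratory chain genes, 1 was higher after S. aureus, 2 were lower and 29 did not pass (1 and 1 adjusted over the list alone), with a median of -0.03, a mean of 0.01 and no call for the list (camera adjusted p = 0.996). The calls were Idh1 (2.07 ± 0.18), Uqcrfs1 (-0.86 ± 0.17) and Cox5a (-0.64 ± 0.18). Among 28 lysosome genes, 0 were higher after S. aureus, 4 were lower and 24 did not pass (0 and 4 adjusted over the list alone, camera adjusted p = 0.271), namely Ctsc (-2.12 ± 0.23), Ctsl (-1.04 ± 0.30), Gla (-0.67 ± 0.12) and Lamp2 (-0.88 ± 0.25). Among 19 genes of the unfolded protein and integrated stress responses, 0 were higher after S. aureus, 2 were lower and 17 did not pass (0 and 2 adjusted over the list alone, camera adjusted p = 0.139), namely Hspa5 (-1.45 ± 0.24) and Ppp1r15a (-1.32 ± 0.31). That list passed with fry (0.0388) and without GAS library A (0.04999). Of 12 conventional dendritic cell markers, 0 were higher after S. aureus, 5 were lower and 7 did not pass (0 and 5 adjusted over the list alone), at a median of -0.91 (camera adjusted p = 0.0356, adjusted p = 0.246 with an estimated correlation). They were Xcr1 (-3.91 ± 0.43), Irf8 (-1.13 ± 0.15), Irf4 (-0.83 ± 0.24), Kmo (-3.05 ± 0.92) and, named after its values were seen, Btla (-3.72 ± 1.17). The list did not pass without GAS library A (0.0586) or S. aureus library B (0.0789), nor with mouse B left out (0.0515) or with fits of 2 groups alone (0.0648). With a filter of 5 CPM its median was -0.54 and it did not pass (0.22).

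Among 11 macrophage markers, 1 was higher after S. aureus, 3 were lower and 7 did not pass (2 and 3 adjusted over the list alone), with a median of 0.10, a mean of -0.09 and no call for the list (camera adjusted p = 0.718). Csf1r (1.33 ± 0.15) was higher, and Fcgr1 (-2.20 ± 0.24), Mertk (-1.18 ± 0.17) and Axl (-0.74 ± 0.23) lower. Of 4 neutrophil markers Mmp9 was higher (2.08 ± 0.54), with a list median of -0.16 and mean of 0.23 (camera adjusted p = 0.862). Of 6 stromal and endothelial markers Kdr was lower (-3.27 ± 0.88), with no call for the list (camera adjusted p = 0.652). The plasmacytoid markers Tcf4 (-1.78 ± 0.29) and Runx2 (-0.81 ± 0.22) and the mast cell and basophil marker Hdc (-2.90 ± 0.54) were lower. For 2 eosinophil, 1 B cell and 2 T and NK cell markers, 0 passed by edgeR, against 0, 0 and 1 at an unadjusted p under 0.05, and 1 T and NK cell marker was higher adjusted over the list alone.

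Steep differences included Tnn, a tenascin gene on chromosome 1 (160085029 to 160153580), with 0 counts after S. aureus and at least 42.9-fold lower than after GAS (edgeR adjusted p = 0.00114), a bound that does not rank it. Olfr1028 had 1 count after S. aureus, a 590.3-fold difference by counts (95% interval 105 to 23368). Angpt1, which encodes a ligand of the endothelial receptor Tie2, was lower, at -6.11 ± 0.50, as were Asap3 at -6.39 ± 0.60, Heatr9 at -6.24 ± 0.50, Plagl1 at -5.72 ± 0.95 and Il27 at -5.83 ± 0.43. Among the genes most in excess after S. aureus were Galnt9 (4.10 ± 0.45), Tacc2 (3.74 ± 0.53), Pald1 (3.49 ± 0.51), Cnr2 (3.37 ± 0.29), the sialyltransferase gene St6gal1 (3.46 ± 0.52) and the fatty acid desaturase gene Scd2 (3.51 ± 0.22). Cd300lb (3.46 ± 0.39), Arrb1 (3.15 ± 0.31), Slc43a2 (3.09 ± 0.30) and Mturn (2.98 ± 0.35) completed the 10 genes with the steepest excess under the rule for naming genes. The same direction in 3 of 3 mice was again a condition for being named here and is no separate support.

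With library totals alone the median of all genes moved from -0.01 to 0.35, 3239 genes were called higher and 1081 lower, and the calls of Gla, Cox5a, Ctsl, Lamp2, Slc2a6, Sod2, Axl, Irf4, Kmo, Runx2, Prdx1 and Btla were lost. Without GAS library A or C or S. aureus library A or C the total of 3274 genes fell to 2138, 2007, 1997 and 2024. Calls of the named genes that a single left-out library ended, with that library and the edgeR adjusted p without it, were those of Slc2a6 (S. aureus A or C, 0.059 to 0.0636), Cox5a (GAS A or C or S. aureus B or C, 0.0679 to 0.108), Ctsl (GAS A or C or S. aureus A, B or C, 0.0527 to 0.116), Lamp2 (GAS A, B or C or S. aureus A, B or C, 0.0529 to 0.0982), Ppp1r15a (GAS C or S. aureus A or C, 0.051 to 0.0521), G6pdx (GAS A or C or S. aureus A or C, 0.0611 to 0.0817), Sod2 (GAS A or C or S. aureus A or C, 0.0566 to 0.0813), Gclm (GAS A or C or S. aureus B or C, 0.0678 to 0.0982), Srxn1 (GAS A or C or S. aureus A, B or C, 0.0625 to 0.141), Mmp9 (GAS A or S. aureus A or C, 0.054 to 0.0803), Axl (GAS A, B or C or S. aureus A, B or C, 0.0571 to 0.152), Irf4 (GAS A, B or C or S. aureus A, B or C, 0.0522 to 0.0963), Kmo (GAS A, B or C or S. aureus A, B or C, 0.0528 to 0.118), Runx2 (GAS A or C or S. aureus A or C, 0.0677 to 0.111), Kdr (GAS B or S. aureus A or C, 0.0673 to 0.0851), Prdx1 (GAS A, B or C or S. aureus A, B or C, 0.0561 to 0.157) and Btla (GAS A, B or C or S. aureus A, B or C, 0.0827 to 0.159). Other alternatives ended calls of named genes too, given with the adjusted p. No filter ended those of Axl (0.0622), Btla (0.0585), Kmo (0.0539), Prdx1 (0.23) and Sod2 (0.0744), length offsets those of Axl (0.0976), Btla (0.0607), Hdc (0.058), Kmo (0.17), Prdx1 (0.275) and Runx2 (0.381), and mouse B left out those of Axl (0.147), Btla (0.0706), Kmo (0.0713), Lamp2 (0.0514) and Prdx1 (0.055). Mouse as a block ended that of Btla (0.0552) and fits of 2 groups alone that of Prdx1 (0.0635). In turn, list members that passed with mouse as a block but not before (log2 fold change, edgeR adjusted p) were Cdh5 (-1.27, 0.0441), Ighm (1.78, 0.00296) and Pdia4 (-0.52, 0.0461).

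**Figure D3:**
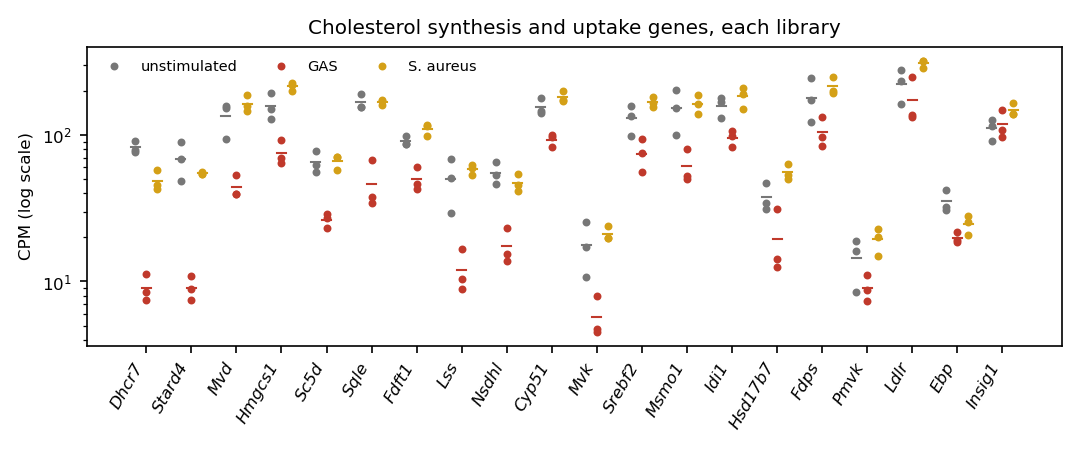
CPM of 20 tested genes of cholesterol synthesis and uptake on a log axis; points are the 3 libraries of each group. For 18 of the 20 genes shown the S. aureus libraries were higher than the GAS libraries at an adjusted p under 0.05.

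The overlap of the 2 infections asked whether the same genes changed in both infected groups. Handling that both infected groups shared, such as gentamicin, cannot be told apart from infection here. Both raised 797 genes, against 185 for independent lists of these sizes, and both lowered 286, against 67.0. Only 5 genes rose after GAS and fell after S. aureus, and 3 did the reverse. Of the 797 genes raised by both, 517 were lower after S. aureus than after GAS, 7 were higher and 273 did not differ at the threshold. Among the 286 lowered by both, 120 were higher after S. aureus and 7 were lower. A further 1961 genes passed as higher after GAS alone, and the direct comparison separated the 2 infections for 1099 of them. For the 2313 lower after GAS alone it did so for 1206, and for the 52 higher and 36 lower after S. aureus alone for 37 and 18.

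Both infections were compared with the same 3 unstimulated libraries, which by itself makes their fold changes correlate. Across the 12693 genes, which are not independent replicates, the fold changes correlated at r = 0.756, against 0.478 ± 0.0205 in 20 simulations without any true change and with shared controls. The covariance was 1.41, 1.25 above the simulated 0.165, and 75.6% of genes had the same sign, against 66.3%. The simulations gave a mean of 0.05 genes higher in both. With 3 controls no division into separate sets of at least 2 each was possible, so the part of the shared calls that rests on the common controls could not be measured. The 797 and 286 shared genes together numbered 1083, and 700 and 672 without S. aureus library B or C.

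**Figure D4:**
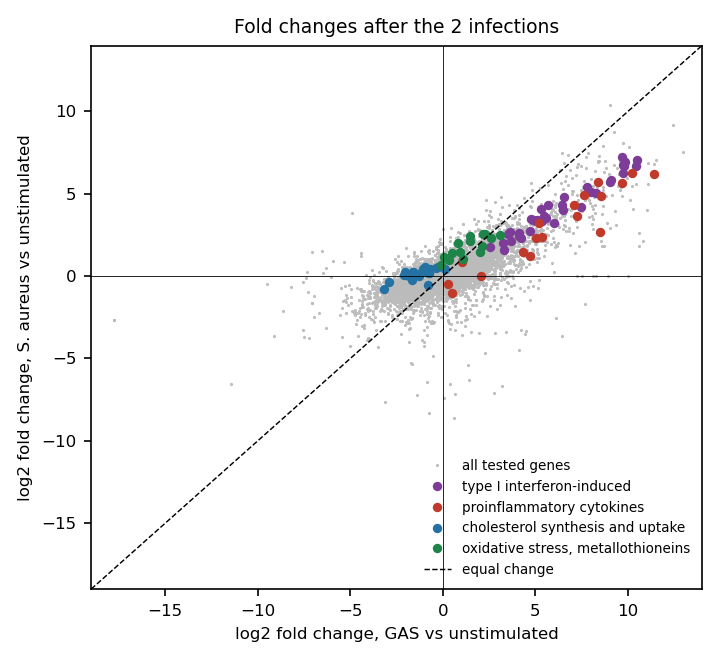
Log2 fold change after S. aureus (vertical) against that after GAS (horizontal), both relative to unstimulated cells, for the 12693 tested genes (grey) and 4 gene lists (colours); the dashed line marks equal change. All 36 type I interferon-induced genes lay below the line and above 0.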

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

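The direct contrast of S. aureus with GAS was a planned test, though the 7 genes here were picked out by their values. Each passed as higher after one infection and lower after the other, and the log2 difference between the infections was itself tested, with n = 3 per group. The chemokine gene Ccl2 stood at 198, 779 and 43.3 CPM in unstimulated, GAS and S. aureus libraries (-4.17 ± 0.64, edgeR adjusted p = 0.00174). Ikzf2, which encodes the transcription factor Helios, stood at 3.61, 9.13 and 1.37 CPM in the same order (-2.73 ± 0.36, edgeR adjusted p = 0.000879). The kinase gene Pim1, a target of cytokine signalling, stood at 141, 304 and 85.9 CPM (-1.82 ± 0.17, edgeR adjusted p = 0.00024), and Wee1, a kinase that holds back mitosis, at 13.9, 23.4 and 8.27 CPM (-1.50 ± 0.18, edgeR adjusted p = 0.000636). Slc6a19, an amino acid transporter gene, stood at 0.227, 4.14 and 0 CPM, and with 0 counts after S. aureus its fitted value (-8.58 ± 0.90, edgeR adjusted p = 0.000765) is no bound, so that it was at least 16.3-fold lower than after GAS. Its unstimulated mean lay under the floor of 3 counts of each S. aureus library, so no fold bound above 1 can be given for its fall after S. aureus. Csf1r stood at 694, 466 and 1172 CPM (1.33 ± 0.15, edgeR adjusted p = 0.000531). Mturn, a gene of neural differentiation, stood at 3.80, 1.28 and 10.2 CPM (2.98 ± 0.35, edgeR adjusted p = 0.000532). The difference between the infections passed for all 7 genes without any single library, but the change after S. aureus itself did not. It lost its call, with that left-out library and the edgeR adjusted p without it, for Ccl2 (unstimulated A or C or S. aureus A, B or C, 0.101 to 0.159), Ikzf2 (unstimulated A, B or C or S. aureus A, B or C, 0.0503 to 0.114), Pim1 (unstimulated A or C or S. aureus A or C, 0.0628 to 0.112), Wee1 (unstimulated A or B or S. aureus A, B or C, 0.0526 to 0.115), Slc6a19 (unstimulated A, B or C or S. aureus A, B or C, 0.0532 to 0.0871), Csf1r (S. aureus C, 0.0635) and Mturn (unstimulated B or S. aureus B or C, 0.0532 to 0.104). The change after GAS lost its call for Ccl2 (GAS A or C, 0.0576 to 0.0692) and Csf1r (GAS A, 0.0504), for Wee1 with library totals (0.17), for Mturn with length offsets (0.0582) and for Ikzf2 with mouse B left out (0.0606). Calls after S. aureus that other alternatives ended, with the adjusted p, were Wee1 (0.0627) with no filter, Ccl2 (0.0977), Ikzf2 (0.0622) and Slc6a19 (0.114) with limma-voom, Ikzf2 (0.0535) and Slc6a19 (0.0652) with mouse as a block, Ikzf2 (0.0789) and Mturn (0.184) with length offsets, Ikzf2 (0.0796), Wee1 (0.137), Slc6a19 (0.121) and Mturn (0.0723) with mouse B left out and Ccl2 (0.0778), Ikzf2 (0.112), Pim1 (0.0673) and Wee1 (0.0916) with 2-group fits. So the calls behind each opposite pair depend on 1 or more single libraries, whereas the call for the difference between the infections does not. Calls were lost at the threshold, while the directions stayed the same for all 7 genes. Whether such changes reflect the bacteria or their dose and survival was not tested, since each bacterium was used at a single dose and time.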

How the results depend on the processing

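Scaling by library totals and leaving out mouse B were tests chosen only after the results were seen. With library totals the genes higher and lower after GAS numbered 1818 and 4708, and those higher and lower after S. aureus than after GAS 3239 and 1081, because the centre of all genes moved. Requiring a fold of at least 2, which can only remove genes, left 1721 genes lower after GAS, 208 lower after S. aureus, and 2099 that differed between the infections, 941 higher and 1158 lower. DESeq2 called 569 genes lower after S. aureus, and the cause was not tested. Leaving out 1 library, which leaves fewer samples, gave 704 to 959 genes changed after S. aureus and 113 to 248 lower. It gave 1997 to 3019 genes that differed between the infections, 813 to 1432 higher and 1134 to 1598 lower, and 672 to 1020 shared by the infections. The lowest totals came without S. aureus library C, at 704 after S. aureus and 672 shared, and without S. aureus library A, at 1997 between the infections. Besides these, the total between the infections fell to 2138, 2007 and 2024 without GAS library A or C or S. aureus library C, and that after S. aureus to 761 without S. aureus library B. Of the values of named genes, lists and counts, 2 reversed, both of the scavenger receptor gene Stab1, singled out after its values were seen. With transcript length offsets it went from 2.01 to -0.31 between the infections and from -0.09 to 1.89 after GAS, and the cause was not tested. With the same offsets 1 of the 4483 genes that passed after GAS in both fits changed direction. Among values of named genes under these alternatives 9243 kept their direction and side of the threshold, 711 fell below it and 141 rose past it. For list tests the numbers were 1013, 52 and 35. Depth limits what is seen for genes at 0, where 3 counts per library set the floor.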

Other observations

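The tests of a mixture of cells and of proliferating cells were chosen only after the results were seen, as was the selection of the genes in this paragraph. The test of GC content and length was also added after the results were seen, though before its own value was. After S. aureus 47 genes were higher than in both other groups and 30 were lower than in both. The genes named here kept their calls against both groups without any single library. Gsta3, a glutathione transferase gene, was higher than after GAS by 2.49 ± 0.48, and Slc39a4, a zinc importer gene, by 1.72 ± 0.37, at 1.68, 2.22 and 7.35 CPM in unstimulated, GAS and S. aureus libraries. The myosin phosphatase gene Ppp1r12b stood at 20.2, 26.4 and 103 CPM (1.97 ± 0.43) and the metal transporter gene Slc11a1 at 77.7, 89.3 and 172 CPM. Klf4, a transcription factor gene of monocyte differentiation, stood at 73.2, 39.8 and 8.50 CPM, and the endocytic adaptor gene Dab2 at 218, 112 and 32.4 CPM. Both were lower after S. aureus than after GAS, at -2.23 ± 0.17 and -1.79 ± 0.16. The cyclin gene Ccne1 (-1.82 ± 0.21) and the receptor gene Cd300lf (-1.55 ± 0.22) were also lower, though Cd300lf did not pass against unstimulated cells without mouse B (edgeR adjusted p = 0.0605).

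The 6 libraries of each comparison can be divided into groups of 3 in 10 ways, which are too few for a share under 0.05. For GAS the real division gave 5365 changed genes and the highest other 0, so that 1 of 10 reached the real value, the real division itself. For S. aureus the numbers were 1179 and 0, and for S. aureus against GAS 3274 and 1, again with 1 of 10. The real division parts all 3 same-mouse pairs, as 3 of the others do, and those gave 0 genes in each comparison.

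The response to S. aureus was smaller than that to GAS in number of changed genes and in the medians of the cytokine, chemokine and interferon lists. A candidate explanation is that fewer cells responded, so that the wells held GAS-like responders mixed with unstimulated cells, which would give every raised gene the same share of its GAS increase. Among genes raised 4-fold or more after GAS the median share was 22.6% for 36 type I interferon-induced genes. It was 8.65% for 14 of the 18 proinflammatory cytokines, a ratio of 2.61 (2-sided permutation test over genes, p = 6e-05). That p takes genes as independent units and does not measure the spread between mice. The unequal shares argue against a mixture with wholly unstimulated cells as the whole cause. They do not exclude fewer responding cells, since cells that changed only some genes were not part of the prediction. The median was 3.89% for 14 chemokines, which spread widely (quartiles 2.69% and 39.6%, highest 258%). It was 76.3% for oxidative stress genes and 19.2% for all genes raised by that much. The GAS libraries held fewer counts on average than the S. aureus libraries (10.6 against 11.1 M), which argues against depth. After every library was thinned to the smallest total, 5267 genes changed for GAS and 1132 for S. aureus, a ratio of 4.65. With totals this close, thinning could change little and adds no further test. A different response to the 2 bacteria, and a different number or survival of bacteria taken up, stay open and were not tested.

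Of 22 cholesterol genes 20 were lower after GAS than after S. aureus, and the call for the list did not hold with an estimated correlation (camera adjusted p = 0.0837). After the trend on GC content and transcript length was removed the list median was 1.61, against 1.38 before, at the smallest p that 10000 random lists can give (0.0001), which argues against such a bias as the whole cause. Loss of proliferating cells would lower cholesterol genes after S. aureus in proportion to cell cycle genes, to -0.39. The median was 0.24 (bootstrap SE 0.0591, over genes and not mice), and the value of -0.39 carries no error. This goes against such a loss as the whole cause only if cell cycle genes did fall after S. aureus. The call for that list did not hold with an estimated correlation (camera adjusted p = 0.359) or with fry (adjusted p = 0.0906). Oxysterol sensing might lower sterol synthesis while raising LXR targets after GAS, but the median difference of the 12 LXR targets was 0.00315 and did not pass with fry. After GAS relative to unstimulated cells their median was -0.13, with 1 higher and 3 lower, and fry passed the list as lower, which goes against oxysterol sensing. No difference had also been set beforehand as counting against it. It is left undecided because Fasn and Scd1, which made up 2 of the 3 falls, also answer to the sterol regulator SREBP. Without them and Srebf1, a choice made after the results were seen, the median of 9 targets was 0.03 after GAS and -0.19 between the infections, and fry passed neither. Members went both ways after GAS, Abcg1 at -1.54 and Arl4c at 1.19. Between the infections they did so too, with Abca1 higher after S. aureus (1.17) and Arl4c lower (-1.51). Oxysterol sensing therefore cannot be told apart from direct control of sterol synthesis by the infection.

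Some oxidative stress genes were higher after S. aureus than after GAS, and NRF2, the regulator of antioxidant genes, is a candidate cause. The 21 NRF2 targets, 9 of which also belong to the oxidative stress list, had a median difference of 0.374, which did not pass with fry but passed with camera, both unadjusted. Of these 21, only G6pdx and Cat passed as higher and Prdx1 and Esd as lower, and G6pdx was 1 of the genes that had raised the question. Gclm (1.16), Srxn1 (0.98) and Gsta3 (2.49), all higher after S. aureus and in GAS highest in library B, were not counted among the 21. Relative to unstimulated cells 8 rose after S. aureus (median 1.12) and 8 after GAS (median 0.51). Missing the fry threshold had been set beforehand as counting against NRF2, but with a positive median and 2 tests that differ a stronger NRF2 response to S. aureus is left open. No technical explanation was tested for this pattern.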
